A study of Mus musculus with 15 samples.

How the data were processed

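Cultured mouse muscle satellite cells, the resident stem cells of skeletal muscle, were profiled by RNA sequencing in 15 libraries. Per the labels' protocols, cells from hindlimb muscle were grown in F10 medium with horse serum and treated for 24 hours. Total RNA was turned into full-length cDNA with the Smart-seq2 protocol, fragmented with Tn5 transposase and made into libraries, again per the labels' protocols. Smart-seq2 does not keep the strand of origin. Batch 1 held 3 DMSO libraries and 3 libraries with 0.05 mM adenosine. Batch 2 held 3 libraries each of DMSO, 0.1 mM adenosine and 0.25 mM adenosine monophosphate (AMP), from C57BL/6J mice per the labels. Groups were taken from the labels of each sample, and every column of the deposited tables could be matched to a sample by name. Nothing in the labels says whether the 3 libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

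The authors deposited raw counts per gene for each batch. Per the submitters' processing notes the tools were Trim Galore, STAR, featureCounts from the Subread package, and DESeq2, with the mm10 genome build. Per the file headers, the batch 1 counts came from featureCounts version 1.6.4 in paired-end mode, with no strand option and an Ensembl annotation of GRCm38. The counter's settings for batch 2 and versions of the other tools are not given in the sources used here. The batch 1 count table listed 46078 genes by identifier, of which 30999 had at least 1 count. The batch 2 count table was deposited by gene symbol and had been filtered before deposit, since its smallest total over the 9 libraries was 101 counts. It had 13106 lines, of which 43 named no gene. These held 0.0589% of the counts and were left out of library totals and tests. Of the 13063 named genes, 13057 matched a batch 1 gene by name and 6 did not. FPKM values were deposited for both batches. Those of batch 1 equalled counts over gene length and library total times a constant of each library between 0.91 and 1.08, so a factor per library had been applied by the authors. The gene lengths behind the deposited FPKM of batch 2 are not in the file, so its scaling could not be rebuilt. Per the file headers, the batch 1 FPKM table also carried the authors' log2 fold changes, which the values show to be coded as DMSO over adenosine, and the authors' adjusted p-values. The deposited gene length of batch 1 is the summed exon length in bases, per the file headers.

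Library totals were 14683346 to 20799588 counts in batch 1 and 11107450 to 14201933 counts in batch 2. Replicates of a group differed by more than counting noise in all 15 pairs, with a chi-square of 3.54 to 34.4 per degree of freedom over genes with at least 20 counts in the pair, so no library looked like a copy of another. The lowest correlation across genes between replicates was 0.981. Deviations from the group means correlated between libraries of the same replicate number by -0.03 to 0.09 in batch 1 (median 0.05, against -0.03 for different numbers) and by -0.07 to 0.30 in batch 2 (median 0.11, against -0.07). Not every pair exceeded 0.1, so the numbers were not taken to pair the samples, although a weak pairing in batch 2 is not excluded. The labels mention no spike-in control, so every value is relative to the other RNA of its library.

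Counts were tested with edgeR version 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group and the quasi-likelihood F test (two-sided, Benjamini-Hochberg adjusted p under 0.05). Batch 1 was fitted on its 6 libraries. The 3 comparisons of batch 2 were fitted on its 9 libraries together, so that all groups shared an estimate of the spread. The difference of the adenosine effect between batches was tested in a fit of all 15 libraries over the 13049 genes in both tables that passed the filter, as an interaction of treatment with batch. Standard errors are the fold change over the square root of the F value. Levels are given as CPM, the usual scaling of counts to the library total, without TMM factors, as mean ± SD over the 3 libraries of a group. A fold change in the text comes from the fit, so it can differ from the ratio of the CPM. Fold changes of batches 1 and 2 were set side by side only as ratios to the DMSO libraries of the same batch, because the tables were made separately.

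A set of 40 gene lists, 31 of pathways and cell programmes and 9 of markers of cell types, was fixed before the data were examined, as were the tests, the rule for named genes and most of the alternative settings. Lists with at least 5 tested members were tested with camera (limma version 3.58.1) against the other genes, with an inter-gene correlation preset at 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. No list of any comparison passed when the correlation was estimated from the data, and that adjusted p is given for each list described. A member of a list rose or fell if its adjusted p over all genes was under 0.05, and the count adjusted over the list alone is given beside it. The genes named are the 8 largest rises and falls of a comparison with DMSO (5 for the difference between the compounds and for that between batches) with adjusted p under 0.05, a mean of at least 10 CPM and every treated library beyond every control library, and up to 4 members of each list with the smallest adjusted p. Predicted gene models and pseudogenes were left out. Members of the satellite cell, purine and cell type lists with at least 10 CPM could also be named with their values. The text leaves some of these genes out. Values of 2 genes that meet the rule are not reported here. Positions are chromosome, start and end in GRCm38 as in the batch 1 count table.

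Reads from ribosomal protein genes can be shared with processed pseudogenes, and those of Hspa1a, Gstm1 and Gbp2 with close paralogs, so their counts are uncertain by the share the counter split or dropped. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart. A group of 6 genes that hold ribosomal RNA or sequence like it (mt-Rnr1, mt-Rnr2, Lars2, Gm26917, Gm23935 and CT010467.1) took 9.86% to 11.7% of the counts with DMSO and 5.54% to 8.11% with adenosine in batch 1, without overlap. In batch 2 they took 18.7% to 20% with DMSO, 17.9% to 22.2% with AMP and 16.2% to 22.1% with adenosine, where replicate 1 stood apart at 22.1% against 16.6% and 16.2%.

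The procedure was tested on 1 set of simulated counts per comparison, drawn from the real means, dispersions and library sizes, with 200 genes of at least 1 CPM changed. Of genes changed 1.5-fold, 2-fold and 4-fold it recovered 24.2%, 50.7% and 87.7% for batch 1 (13842 genes in the simulation), 41.8%, 76.1% and 92.4% for adenosine in batch 2 (13063 genes) and 10.4%, 46.3% and 92.4% for the difference between batches (13049 genes). It called 3 of 13261, 13 of 12854 and 10 of 12843 unchanged genes. Far more genes were called in the data, so these rates need not hold there. Small changes could still go undetected. A simulated list shifted 1.4-fold was called in both batches, with 0 other lists in batch 1 and 1 in batch 2. Correlation between genes was not simulated, so its preset was not tested.

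Alternative settings fixed at the start were DESeq2 version 1.42.0, limma-voom, DESeq2's size factors in edgeR, no filter, a mean of at least 10 CPM, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with a mean FPKM of at least 1, limma-trend on log2(FPKM + 1) without that filter, a replicate block, a correlation estimated from the data for the lists, fits of only the groups compared, counts thinned to the smallest library and leaving out each library in turn. Library totals without TMM factors, and a fit without the 6 ribosomal RNA-like genes, were added after seeing the data. The 3 DMSO libraries of batch 2 serve both comparisons of that batch. Chance agreement between these was therefore taken from 20 simulations of unchanged groups against the same controls. Tests of technical and other explanations were coded after the first results had been seen, and the closing parts name the test that was chosen only after its own outcome was known.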

Results

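Satellite cells of mouse hindlimb muscle were treated in culture for 24 hours with DMSO, with the nucleoside adenosine or with AMP, which is adenosine carrying a 5' phosphate. Adenosine was given at 0.05 mM in batch 1 and at 0.1 mM in batch 2, so its dose and the batch changed together. AMP was given at 0.25 mM in batch 2. Each group had 3 libraries, and all fold changes are relative to the DMSO libraries of the same batch.

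Adenosine lowered Mki67 and raised Arg2 in batch 1. Mki67, a marker of cycling cells, had 53 ± 45.4 CPM with DMSO and 0.772 ± 0.35 CPM with adenosine (SD, n = 3 per group), a log2 fold change of -6.30 (SE 0.61, adjusted p = 9.14e-06). Top2a was 50.1-fold lower, Aurkb 63.7-fold lower, Cdk1 42.5-fold lower and Ccna2 49.4-fold lower with adenosine. The mitochondrial arginase gene Arg2 (chromosome 12, 79130777 to 79156301) rose from 0.473 ± 0.271 to 67.7 ± 30.5 CPM, a log2 fold change of 6.92 (SE 0.41, adjusted p = 3.53e-07). Of 13842 genes tested in batch 1, 5420 had an adjusted p under 0.05, 2714 of them higher and 2706 lower with adenosine. Of these, 1278 rose and 1392 fell by more than 2-fold. All 3 adenosine libraries lay beyond all 3 DMSO libraries for 53.6% of tested genes, against 10% by chance. The balance of rises and falls depended on the scaling, since library totals without TMM factors, tried after the data were seen, gave 4030 rises and 1948 falls and moved the median log2 fold change of all genes to 0.225.

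Among genes with a mean of at least 10 CPM and separated groups, the largest fall in batch 1 was that of the imprinted long non-coding RNA H19 (chromosome 7, 142575529 to 142578143), which went from 76.4 ± 46.9 to 0.983 ± 0.676 CPM and was 89.3-fold lower with adenosine. C1qtnf3, which codes for a secreted protein, was 73.3-fold lower. Among the largest rises were the protocadherin gene Pcdh17 (40.5-fold higher) and the imprinted non-coding RNAs Rian (20.8-fold higher) and Meg3 (15.6-fold higher), neighbours on chromosome 12. Meg3 (chromosome 12, 109541001 to 109571726) rose from 4.81 ± 1.1 to 86.8 ± 16.3 CPM. Counting was done without strand, so transcripts antisense to these genes cannot be told apart from them. Fosb, Arrdc4, Ppl and Chst8 rose by log2 fold changes of 4.11, 3.98, 3.90 and 3.66.

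With adenosine in batch 1, 21 of 34 tested gene lists passed the threshold, 7 upward and 14 downward, and 0 of these passed in camera with an estimated correlation (23 lists had an unadjusted p under 0.05 with the preset correlation). Among the 40 genes of mitosis, 1 rose, 39 fell and 0 were not called (1 and 39 adjusted over the list alone), with a median log2 fold change of -3.97 (adjusted p = 1.60e-25, or adjusted p = 0.316 with an estimated correlation). The 46 genes of DNA replication and S phase had a median of -1.84 (adjusted p = 1.94e-36, or adjusted p = 0.294 with an estimated correlation), and 0 rose, 42 fell and 4 were not called (0 and 43 adjusted over the list alone). Uhrf1 and Rrm2 fell, with log2 fold changes of -3.89 and -3.57. For ribosomal proteins the median was -0.95 over 74 genes (adjusted p = 9.84e-26, or adjusted p = 0.316 with an estimated correlation), where 0 rose, 60 fell and 14 were not called (0 and 62 adjusted over the list alone). Without the 6 genes like ribosomal RNA this median was -0.948. Rps2 fell from 3668 ± 448 to 1197 ± 69 CPM. Among the 25 genes of cholesterol synthesis, 0 rose, 17 fell and 8 were not called (0 and 22 adjusted over the list alone), with a median log2 fold change of -0.58 (adjusted p = 3.22e-06, or adjusted p = 0.538 with an estimated correlation). The 10 genes of fatty acid synthesis had a median of -0.86 (adjusted p = 1.18e-04, or adjusted p = 0.316 with an estimated correlation), and 1 rose, 8 fell and 1 was not called (1 and 8 adjusted over the list alone). Elovl6 was 4.13-fold lower and Scd1 3-fold lower. For endoplasmic reticulum chaperones of the unfolded protein response the median was -0.48 over 17 genes (adjusted p = 0.00134, or adjusted p = 0.489 with an estimated correlation), where 1 rose, 9 fell and 7 were not called (1 and 9 adjusted over the list alone). Herpud1 and Xbp1 fell, and Dnajb9 rose by a log2 fold change of 1.42. Among the 36 genes of the integrated stress response, driven by ATF4, 5 rose, 16 fell and 15 were not called (6 and 18 adjusted over the list alone), with a median log2 fold change of -0.31 (adjusted p = 0.0043, or adjusted p = 0.542 with an estimated correlation). Phgdh was 4.88-fold lower, whereas Atf3 was 9.12-fold higher. With library totals the medians of cholesterol synthesis, these chaperones and the integrated stress response were -0.388, -0.283 and -0.111.

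Nqo1 (chromosome 8, 107388225 to 107403206), a target of the transcription factor NRF2, rose with adenosine in batch 1 from 26.4 ± 3.97 to 204 ± 6.88 CPM (SD, n = 3 per group), a log2 fold change of 2.76 (SE 0.14, adjusted p = 1.55e-07). Gstm1, whose reads can be shared with its close family members, was 5.97-fold higher. Out of 16 genes of NRF2 oxidative stress, 13 rose, 0 fell and 3 were not called (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.75 (adjusted p = 9.38e-14, or adjusted p = 0.294 with an estimated correlation). The 27 genes of p53 targets had a median of 0.63 (adjusted p = 1.74e-05, or adjusted p = 0.316 with an estimated correlation), and 15 rose, 2 fell and 10 were not called (16 and 3 adjusted over the list alone). Btg2 was 3-fold higher and Trp53inp1 3.36-fold higher. For the cAMP and CREB response the median was 1.16 over 16 genes (adjusted p = 3.61e-05, or adjusted p = 0.294 with an estimated correlation), where 11 rose, 0 fell and 5 were not called (11 and 0 adjusted over the list alone). Nr4a2 was 8.71-fold higher and Dusp1 3.1-fold higher. Out of 12 genes of FOXO targets, 6 rose, 0 fell and 6 were not called (6 and 0 adjusted over the list alone), with a median log2 fold change of 0.47 (adjusted p = 0.00465, or adjusted p = 0.316 with an estimated correlation). Without adenosine replicate 1 this median was 0.30. Txnip rose from 37 ± 5.3 to 238 ± 29.2 CPM. The 21 genes of autophagy and lysosome had a median of 0.60 (adjusted p = 8.93e-07, or adjusted p = 0.294 with an estimated correlation), and 16 rose, 0 fell and 5 were not called (16 and 0 adjusted over the list alone). Gpnmb was 12.6-fold higher. For hypoxia the median was 0.76 over 14 genes (adjusted p = 4.10e-04, or adjusted p = 0.316 with an estimated correlation), where 9 rose, 2 fell and 3 were not called (10 and 2 adjusted over the list alone). Ndrg1 was 3.65-fold higher and Adm 2.81-fold higher.

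The myogenic regulator Myod1 (chromosome 7, 46376474 to 46379092) fell with adenosine in batch 1 from 2735 ± 127 to 1168 ± 223 CPM, a log2 fold change of -1.42 (SE 0.14, adjusted p = 1.15e-05). Ncam1 was 5.92-fold lower, Des 3.55-fold lower, Nes 4.64-fold lower and Ccnd1 2.01-fold lower, and Myf5 fell, with a log2 fold change of -0.67. Out of 16 genes of satellite cell activation, 2 rose, 9 fell and 5 were not called (2 and 10 adjusted over the list alone), with a median log2 fold change of -0.57 (adjusted p = 4.27e-04, or adjusted p = 0.294 with an estimated correlation). Pax7, a marker of satellite cells, was not called, with a log2 fold change of -0.16 (SE 0.13, adjusted p = 0.367). The 20 genes of satellite cell quiescence had a median of -0.21 (adjusted p = 0.631, or adjusted p = 0.768 with an estimated correlation), and 5 rose, 7 fell and 8 were not called (5 and 7 adjusted over the list alone). Notch3, Gas1 and Fgfr4 of that list fell, with log2 fold changes of -2.50, -1.86 and -1.72. For extracellular matrix the median was -0.34 over 27 genes (adjusted p = 0.00679, or adjusted p = 0.542 with an estimated correlation), where 4 rose, 13 fell and 10 were not called (4 and 14 adjusted over the list alone). Col3a1 was 9.43-fold lower. Library totals gave -0.142 for this median and -0.378 for that of satellite cell activation.

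The adenosine receptor gene Adora2b (chromosome 11, 62248984 to 62266453) fell in batch 1 from 6.12 ± 1.28 to 0.245 ± 0.198 CPM, a log2 fold change of -4.77 (SE 0.54, adjusted p = 3.21e-05). P2ry2 was 2.51-fold lower and P2rx4 1.66-fold higher, the latter with adjusted p = 0.0587 in limma-trend on log2(FPKM + 1) without a filter. Adk, which codes for adenosine kinase, was 2.2-fold lower, the nucleoside transporter gene Slc29a1 1.88-fold lower and Ahcy 2.61-fold lower, while the ectonucleotidase gene Enpp1 was 10.6-fold higher. Out of 7 genes of purine receptors, 2 rose, 2 fell and 3 were not called (3 and 2 adjusted over the list alone), with a median log2 fold change of 0.06 (adjusted p = 0.631, or adjusted p = 0.722 with an estimated correlation). For nucleoside transport and purine turnover the median was -0.00176 over 17 genes (adjusted p = 0.564, or adjusted p = 0.641 with an estimated correlation), where 3 rose, 6 fell and 8 were not called (5 and 6 adjusted over the list alone). In both lists the median, mean and test differed in sign.

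The calls of 6 further lists in batch 1 depended on single libraries or settings. Among the 17 genes of de novo purine synthesis, 2 rose, 9 fell and 6 were not called (2 and 9 adjusted over the list alone), with a median log2 fold change of -0.31 (adjusted p = 0.042, or adjusted p = 0.542 with an estimated correlation). Its adjusted p was 0.0769 without DMSO replicate 1, 0.0661 without adenosine replicate 1, 0.0611 with a replicate block, 0.0809 among genes with a mean of at least 10 CPM and 0.139 with library totals, which gave a median of -0.113. The 13 genes of pyrimidine synthesis and salvage had a median of -0.16 (adjusted p = 0.037, or adjusted p = 0.316 with an estimated correlation), and 0 rose, 5 fell and 8 were not called (0 and 5 adjusted over the list alone). With library totals its median log2 fold change was 0.0423 and its adjusted p 0.0705, and among genes with a mean of at least 10 CPM its adjusted p was 0.0654. Without adenosine replicate 2 the median was -0.255. For myogenic differentiation the median was -0.89 over 26 genes (adjusted p = 0.0392, or adjusted p = 0.627 with an estimated correlation), where 1 rose, 7 fell and 18 were not called (1 and 7 adjusted over the list alone). Without DMSO replicate 1, adenosine replicate 1 or adenosine replicate 3, its adjusted p was 0.0872, 0.0733 or 0.0874, and it was 0.0567 among genes with a mean of at least 10 CPM. The median was -0.532 without DMSO replicate 1, -1.54 without adenosine replicate 2 and -0.505 without adenosine replicate 3. Chrna1 of this list was 3.88-fold lower. Among the 11 genes of the Notch pathway, 1 rose, 6 fell and 4 were not called (1 and 6 adjusted over the list alone), with a median log2 fold change of -0.33 (adjusted p = 0.0433, or adjusted p = 0.542 with an estimated correlation). This became 0.081 without DMSO replicate 2, 0.0623 without adenosine replicate 3 and 0.0525 with library totals, which gave a median of -0.13, against -0.59 among genes with a mean of at least 10 CPM. The 18 genes of the TGF-beta and YAP response had a median of -0.47 (adjusted p = 0.042, or adjusted p = 0.538 with an estimated correlation), and 4 rose, 9 fell and 5 were not called (4 and 9 adjusted over the list alone). Without the same libraries its adjusted p was 0.0626 and 0.0684, and with library totals 0.0635, with a median of -0.271 there and of -0.918 among genes with a mean of at least 10 CPM. Acta2 was 12.4-fold lower. For the interferon response the median was 0.90 over 23 genes (adjusted p = 0.037, or adjusted p = 0.542 with an estimated correlation), where 11 rose, 3 fell and 9 were not called (11 and 3 adjusted over the list alone). Its adjusted p was 0.0633 without DMSO replicate 3, 0.0755 without adenosine replicate 2, 0.0838 with library totals and 0.51 among genes with a mean of at least 10 CPM, where the median was 0.0705, so the median of 0.90 rests on less abundant members.

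Of markers of other cell types, 2 of 16 for leukocytes were tested in batch 1, too few to show such cells. Both rose (2 and 0 adjusted over the list alone), Cd68 from 1.86 ± 0.693 to 12.9 ± 1.83 CPM. Both tested smooth muscle and pericyte markers fell (0 and 2), Cspg4 from 2.73 ± 1.23 to 1.01 ± 0.531 CPM. Gsn of the fibro-adipogenic progenitor list had 117 ± 17.5 CPM with DMSO and was not called, with a log2 fold change of -0.47 (SE 0.22, adjusted p = 0.11), but passed without adenosine replicate 1 (adjusted p = 0.00331), with a replicate block (0.0212) and without the filter on low counts (0.00194). Without that library it had -0.86. Of the adult myofibre list, Mylk2 was 5.42-fold higher and Eno3 3.1-fold lower.

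**Figure D1:**
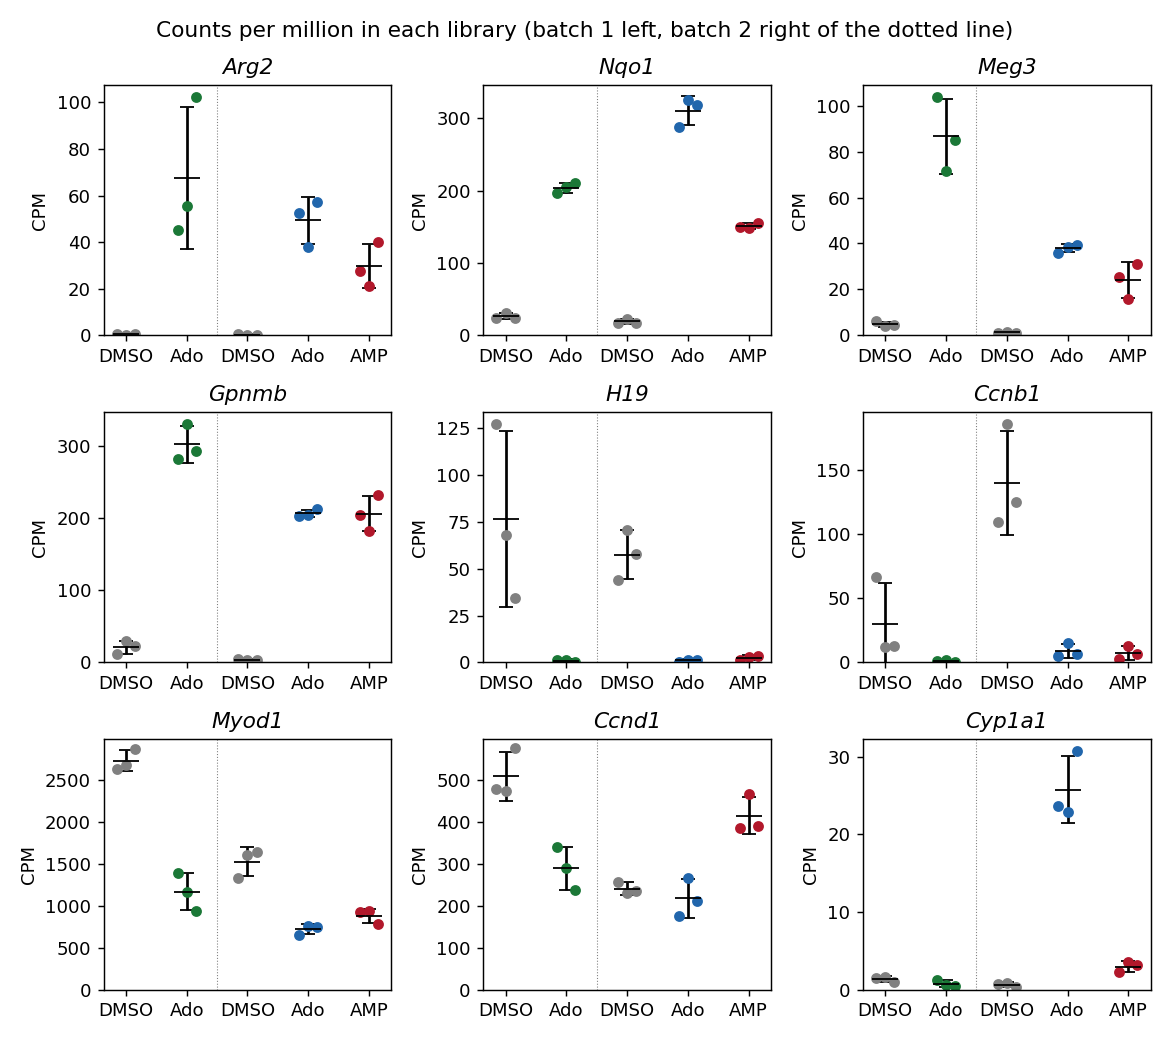
CPM of 9 genes in each of the 15 libraries, with points for libraries and bars for the mean ± SD of a group. Nqo1 lies at 26.4 ± 3.97 CPM with DMSO and 204 ± 6.88 CPM with adenosine in batch 1.

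Adenosine at 0.1 mM in batch 2 lowered Ccnb1 and raised Arg2. Ccnb1 (chromosome 13, 100778650 to 100786570) fell from 140 ± 40.4 to 8.72 ± 5.52 CPM (SD, n = 3 per group), a log2 fold change of -4.31 (SE 0.37, adjusted p = 6.38e-08). Cep55 was 21.3-fold lower, Anln 19.4-fold lower and Iqgap3 17.9-fold lower. Arg2 rose from 0.308 ± 0.1 to 49.3 ± 10.2 CPM, a log2 fold change of 6.95 (SE 0.33, adjusted p = 1.34e-10). Gpnmb (chromosome 6, 49036518 to 49058182) rose from 3.58 ± 0.875 to 206 ± 5.16 CPM and was 46-fold higher. Of 13063 genes tested, 9067 had an adjusted p under 0.05, 4559 of them higher and 4508 lower. More than 2-fold rises and falls numbered 2318 and 1875. All adenosine libraries lay beyond all DMSO libraries for 74.6% of tested genes, against 10% by chance. Library totals without TMM factors gave 6344 rises and 2891 falls and a median log2 fold change of all genes of 0.323.

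By the same criteria H19 was again the largest fall, from 57.5 ± 13.2 to 1.08 ± 0.66 CPM with adenosine in batch 2, and C1qtnf3 was 20.2-fold lower. Pknox2 and Olfml2b were 19.2-fold lower and 18.3-fold lower. Pcdh17 was 106-fold higher, Tex14 55.1-fold higher, Ppl 34.1-fold higher, Tcim 33.5-fold higher and Chst8 30.4-fold higher. Cyp1a1 (chromosome 9, 57697613 to 57703822), a target of the aryl hydrocarbon receptor, rose from 0.655 ± 0.295 to 25.8 ± 4.33 CPM. Meg3 was 23.7-fold higher.

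In batch 2, 21 of 32 tested lists passed with adenosine, 8 upward and 13 downward, and 0 did so in camera with an estimated correlation (21 lists had an unadjusted p under 0.05 with the preset correlation). Among the 40 genes of mitosis, 1 rose, 39 fell and 0 were not called (1 and 39 adjusted over the list alone), with a median log2 fold change of -3.61 (adjusted p = 2.66e-14, or adjusted p = 0.239 with an estimated correlation). Incenp fell, with a log2 fold change of -2.69, and Pttg1 rose by 1.67. The 46 genes of DNA replication and S phase had a median of -1.70 (adjusted p = 5.86e-23, or adjusted p = 0.144 with an estimated correlation), and 0 rose, 45 fell and 1 was not called (0 and 45 adjusted over the list alone). Mcm5 was 3.56-fold lower. For ribosomal proteins the median was -0.97 over 74 genes (adjusted p = 5.86e-23, or adjusted p = 0.233 with an estimated correlation), where 0 rose, 69 fell and 5 were not called (0 and 70 adjusted over the list alone). Rpl7a was 4.14-fold lower. Among the 40 genes of ribosome biogenesis, 0 rose, 35 fell and 5 were not called (0 and 35 adjusted over the list alone), with a median log2 fold change of -0.50 (adjusted p = 3.46e-07, or adjusted p = 0.237 with an estimated correlation). Npm1 was 3.84-fold lower. The 25 genes of cholesterol synthesis had a median of -0.85 (adjusted p = 1.26e-11, or adjusted p = 0.0936 with an estimated correlation), and 0 rose, 24 fell and 1 was not called (0 and 24 adjusted over the list alone). Hmgcs1 was 3.08-fold lower. For fatty acid synthesis the median was -1.15 over 10 genes (adjusted p = 5.79e-07, or adjusted p = 0.0936 with an estimated correlation), where 1 rose, 8 fell and 1 was not called (1 and 8 adjusted over the list alone). Among the 17 genes of glycolysis, 1 rose, 13 fell and 3 were not called (1 and 14 adjusted over the list alone), with a median log2 fold change of -0.78 (adjusted p = 1.39e-04, or adjusted p = 0.144 with an estimated correlation). Ldha was 2.18-fold lower. The medians of ribosome biogenesis, cholesterol synthesis and glycolysis were -0.192, -0.546 and -0.476 with library totals.

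Adk fell with adenosine in batch 2, from 112 ± 5.62 to 35.4 ± 5.79 CPM, a log2 fold change of -1.97 (SE 0.10, adjusted p = 2.33e-10), and Slc29a1 was 3.48-fold lower. Adora2b was 11.6-fold lower and P2ry2 4.29-fold lower, whereas P2rx4 was 2.41-fold higher. Xdh (chromosome 17, 73883908 to 73950182), which codes for xanthine dehydrogenase, rose from 1.29 ± 0.0806 to 20.4 ± 2.15 CPM. Out of 17 genes of de novo purine synthesis, 0 rose, 15 fell and 2 were not called (0 and 15 adjusted over the list alone), with a median log2 fold change of -0.67 (adjusted p = 2.31e-07, or adjusted p = 0.0576 with an estimated correlation). Mthfd2 and Pfas were 4.62-fold lower and 2.65-fold lower. The 13 genes of pyrimidine synthesis and salvage had a median of -0.67 (adjusted p = 4.37e-04, or adjusted p = 0.144 with an estimated correlation), and 0 rose, 11 fell and 2 were not called (0 and 11 adjusted over the list alone). Tk1 was 8.8-fold lower. These 2 medians were -0.364 and -0.363 with library totals. For nucleoside transport and purine turnover the median was -0.23 over 16 genes (adjusted p = 0.15, or adjusted p = 0.239 with an estimated correlation), where 4 rose, 7 fell and 5 were not called (4 and 7 adjusted over the list alone). Out of 7 genes of purine receptors, 4 rose, 2 fell and 1 was not called (4 and 2 adjusted over the list alone), with a median log2 fold change of 0.42 (adjusted p = 0.886, or adjusted p = 0.937 with an estimated correlation). For the receptors the median, mean and test differed in sign.

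In batch 2, Nqo1 rose from 19.3 ± 3.31 to 310 ± 20.1 CPM. Of the 16 genes of NRF2 oxidative stress, 13 rose, 2 fell and 1 was not called (13 and 3 adjusted over the list alone), with a median log2 fold change of 0.93 (adjusted p = 2.46e-10, or adjusted p = 0.0936 with an estimated correlation). The 21 genes of autophagy and lysosome had a median of 0.76 (adjusted p = 4.90e-10, or adjusted p = 0.0576 with an estimated correlation), and 19 rose, 1 fell and 1 was not called (19 and 1 adjusted over the list alone). Map1lc3b was 4.03-fold higher. For FOXO targets the median was 1.45 over 12 genes (adjusted p = 1.18e-05, or adjusted p = 0.0936 with an estimated correlation), where 9 rose, 1 fell and 2 were not called (9 and 1 adjusted over the list alone). Txnip was 15.2-fold higher and Irs2 5.71-fold higher. Of the 27 genes of p53 targets, 18 rose, 5 fell and 4 were not called (18 and 5 adjusted over the list alone), with a median log2 fold change of 0.47 (adjusted p = 1.18e-05, or adjusted p = 0.133 with an estimated correlation). Btg2 was 6.33-fold higher. The 15 genes of the cAMP and CREB response had a median of 1.25 (adjusted p = 9.51e-06, or adjusted p = 0.0936 with an estimated correlation), and 12 rose, 2 fell and 1 was not called (12 and 2 adjusted over the list alone). For hypoxia the median was 0.44 over 14 genes (adjusted p = 5.15e-04, or adjusted p = 0.144 with an estimated correlation), where 8 rose, 2 fell and 4 were not called (8 and 2 adjusted over the list alone). Adm was 6.94-fold higher and Vegfa 6.21-fold higher. Of the 17 genes of endoplasmic reticulum chaperones, 2 rose, 14 fell and 1 was not called (2 and 14 adjusted over the list alone), with a median log2 fold change of -1.03 (adjusted p = 5.33e-05, or adjusted p = 0.144 with an estimated correlation). Hsp90b1 was 2.72-fold lower. The 35 genes of the integrated stress response had a median of -0.54 (adjusted p = 0.00344, or adjusted p = 0.301 with an estimated correlation), and 10 rose, 23 fell and 2 were not called (10 and 23 adjusted over the list alone). Asns was 4.03-fold lower and Ddit4 8.67-fold higher. Library totals gave p53 targets, hypoxia and the integrated stress response medians of 0.776, 0.752 and -0.239.

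Myod1 fell with adenosine in batch 2 from 1530 ± 172 to 719 ± 59.4 CPM, and Ncam1 was 5.42-fold lower and Myf5 1.86-fold lower. Ccnd1 fell, with a log2 fold change of -0.46, which was -0.15 (adjusted p = 0.273) with library totals. Pax7 rose by a log2 fold change of 0.35, Foxo1 by 1.03 and Foxo3 by 0.94. With library totals Pax7 had 0.66 and Myf5 -0.59. Out of 16 genes of satellite cell activation, 3 rose, 12 fell and 1 was not called (3 and 12 adjusted over the list alone), with a median log2 fold change of -0.69 (adjusted p = 0.00268, or adjusted p = 0.144 with an estimated correlation). For satellite cell quiescence the median was 0.16 over 20 genes (adjusted p = 0.957, or adjusted p = 0.976 with an estimated correlation), where 9 rose, 8 fell and 3 were not called (9 and 9 adjusted over the list alone). Its median, mean and test differed in sign. The 27 genes of extracellular matrix had a median of -0.81 (adjusted p = 0.00621, or adjusted p = 0.559 with an estimated correlation), and 4 rose, 18 fell and 5 were not called (4 and 18 adjusted over the list alone). Lama2 was 8.77-fold lower and Bgn 9.45-fold lower. Using library totals, satellite cell activation had a median of -0.381 and extracellular matrix of -0.495. Out of 21 genes of the interferon response, 15 rose, 3 fell and 3 were not called (15 and 3 adjusted over the list alone), with a median log2 fold change of 1.61 (adjusted p = 0.00107, or adjusted p = 0.0936 with an estimated correlation). Ifi35 was 3.68-fold higher. The 17 genes of NF-kB and inflammation had a median of 1.19 (adjusted p = 0.00344, or adjusted p = 0.239 with an estimated correlation), and 11 rose, 1 fell and 5 were not called (12 and 1 adjusted over the list alone). Among genes with a mean of at least 10 CPM that median was 0.568. Cx3cl1 was 2.29-fold higher. The 2 tested of 16 leukocyte markers rose (2 and 0 adjusted over the list alone), Cd68 from 2.48 ± 0.809 to 11.8 ± 1.27 CPM. The 1 tested smooth muscle and pericyte marker, Cspg4, fell from 1.83 ± 0.428 to 0.413 ± 0.154 CPM.

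Fold changes of adenosine in the 2 batches were correlated across 12607 genes (Pearson r = 0.834, Spearman rho = 0.817), and 80.9% of genes had the same sign. Genes are not independent replicates, so no p is given. Arg2 had log2 fold changes of 6.92 and 6.95, H19 of -6.48 and -6.02, and Myod1 of -1.42 and -1.40. Genes that rose in both batches numbered 2218, against 876.8 if the calls were independent, and 2369 fell in both, against 916. Of 4622 genes called in both, 35 went in opposite directions.

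**Figure D2:**
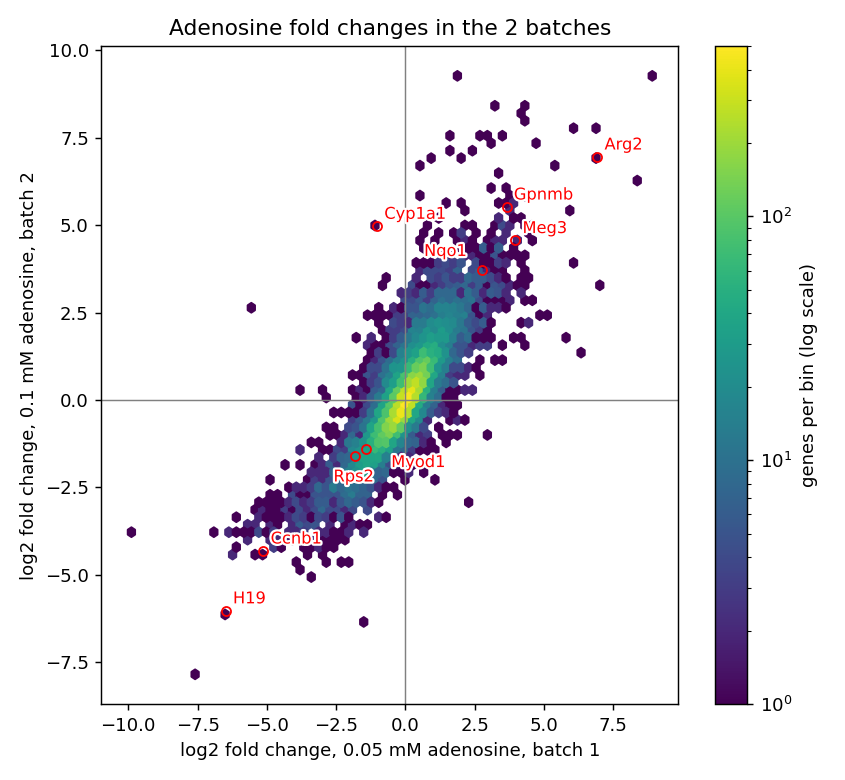
Log2 fold change of adenosine over DMSO in batch 1 (x) and batch 2 (y) for genes tested in both, as a density of hexagons with 9 genes labelled. Pearson r across genes is 0.834.

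AMP at 0.25 mM lowered Ccnb1 and raised Arg2, as adenosine did in batch 2. Ccnb1 fell from 140 ± 40.4 to 7.55 ± 5.23 CPM (SD, n = 3 per group), a log2 fold change of -4.48 (SE 0.38, adjusted p = 8.14e-08). Kif11 was 20.6-fold lower, Kif4 21.3-fold lower and Cep55 25.2-fold lower. Arg2 rose from 0.308 ± 0.1 to 29.6 ± 9.49 CPM, a log2 fold change of 6.25 (SE 0.35, adjusted p = 9.06e-10). Gpnmb was 47.2-fold higher and H19 26.6-fold lower. AMP changed 8564 of 13063 tested genes, 4405 upward and 4159 downward, of which 2110 and 1507 by more than 2-fold. All AMP libraries lay beyond all DMSO libraries for 70.8% of tested genes, against 10% by chance. With library totals the split was 6037 and 2605, and the median log2 fold change of all genes was 0.279. Other large rises were those of Ppl (4.81), Lncpint (4.41), Arrdc4 (4.26), Meg3 (3.95), Sod3 (3.86) and Dyrk1b (3.78), all as log2 fold changes.

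With AMP, 19 of 32 lists passed, 8 upward and 11 downward, and 0 in camera with an estimated correlation (20 lists had an unadjusted p under 0.05 with the preset correlation). Among the 40 genes of mitosis, 1 rose, 39 fell and 0 were not called (1 and 39 adjusted over the list alone), with a median log2 fold change of -3.79 (adjusted p = 9.32e-20, or adjusted p = 0.204 with an estimated correlation). The 46 genes of DNA replication and S phase had a median of -1.70 (adjusted p = 2.19e-30, or adjusted p = 0.0822 with an estimated correlation), and 0 rose, 46 fell and 0 were not called (0 and 46 adjusted over the list alone). Rpa2 was 3.81-fold lower. For ribosomal proteins the median was -0.90 over 74 genes (adjusted p = 1.78e-23, or adjusted p = 0.206 with an estimated correlation), where 0 rose, 70 fell and 4 were not called (0 and 70 adjusted over the list alone). Rpl7 was 2.88-fold lower. Among the 25 genes of cholesterol synthesis, 0 rose, 23 fell and 2 were not called (0 and 23 adjusted over the list alone), with a median log2 fold change of -0.95 (adjusted p = 6.68e-17, or adjusted p = 0.0627 with an estimated correlation). Hmgcs1 was 3.28-fold lower. The 10 genes of fatty acid synthesis had a median of -1.38 (adjusted p = 1.57e-09, or adjusted p = 0.0578 with an estimated correlation), and 1 rose, 9 fell and 0 were not called (1 and 9 adjusted over the list alone). Of the 17 genes of endoplasmic reticulum chaperones, 2 rose, 14 fell and 1 was not called (2 and 14 adjusted over the list alone), with a median log2 fold change of -0.96 (adjusted p = 1.57e-09, or adjusted p = 0.0629 with an estimated correlation).

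Nqo1 rose with AMP from 19.3 ± 3.31 to 151 ± 3.79 CPM, and Txnip was 11.6-fold higher. Among the 16 genes of NRF2 oxidative stress, 13 rose, 3 fell and 0 were not called (13 and 3 adjusted over the list alone), with a median log2 fold change of 0.51 (adjusted p = 7.11e-07, or adjusted p = 0.131 with an estimated correlation). For the cAMP and CREB response the median was 1.23 over 15 genes (adjusted p = 2.07e-05, or adjusted p = 0.0682 with an estimated correlation), where 11 rose, 1 fell and 3 were not called (11 and 1 adjusted over the list alone). Of the 21 genes of autophagy and lysosome, 17 rose, 1 fell and 3 were not called (18 and 1 adjusted over the list alone), with a median log2 fold change of 0.52 (adjusted p = 1.30e-08, or adjusted p = 0.0578 with an estimated correlation). Map1lc3b was 3.33-fold higher. The NRF2 and autophagy lists had medians of 0.776 and 0.778 with library totals. For the interferon response the median was 1.58 over 21 genes (adjusted p = 6.23e-04, or adjusted p = 0.0805 with an estimated correlation), where 16 rose, 3 fell and 2 were not called (16 and 3 adjusted over the list alone). Out of 17 genes of NF-kB and inflammation, 16 rose, 0 fell and 1 was not called (16 and 0 adjusted over the list alone), with a median log2 fold change of 1.52 (adjusted p = 2.41e-07, or adjusted p = 0.0837 with an estimated correlation). Cxcl1 was 5.66-fold higher, Ccl7 6.35-fold higher and Lif 5.52-fold higher. With AMP the 2 tested of 16 leukocyte markers rose (2 and 0 adjusted over the list alone), Cd68 to 12.4 ± 1.68 CPM. Cspg4 fell to 0.53 ± 0.189 CPM.

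Adk fell with AMP from 112 ± 5.62 to 35.7 ± 2.27 CPM, a log2 fold change of -1.92 (SE 0.10, adjusted p = 4.81e-10). Slc29a1 was 2.84-fold lower, Adora2b 4.96-fold lower and Xdh 10.3-fold higher. P2ry2 fell, with a log2 fold change of -0.66 (adjusted p = 0.00856, and 0.0749 with library totals), which was -0.437 without AMP replicate 3 and -0.404 with library totals. Of the 17 genes of de novo purine synthesis, 0 rose, 15 fell and 2 were not called (0 and 15 adjusted over the list alone), with a median log2 fold change of -0.65 (adjusted p = 9.06e-08, or adjusted p = 0.0578 with an estimated correlation). Paics was 2.22-fold lower. The 13 genes of pyrimidine synthesis and salvage had a median of -0.49 (adjusted p = 1.87e-04, or adjusted p = 0.135 with an estimated correlation), and 0 rose, 12 fell and 1 was not called (0 and 12 adjusted over the list alone). These 2 medians were -0.387 and -0.222 with library totals. Of satellite cell genes, Myod1 was 2.08-fold lower and Ncam1 2.92-fold lower, whereas Pax7 was 1.54-fold higher and Ccnd1 1.43-fold higher, a log2 fold change of 0.52, or 0.78 with library totals. For satellite cell activation the median was -0.40 over 16 genes (adjusted p = 0.123, or adjusted p = 0.367 with an estimated correlation), where 5 rose, 8 fell and 3 were not called (5 and 8 adjusted over the list alone). The 27 genes of extracellular matrix had a median of -0.36 (adjusted p = 0.217, or adjusted p = 0.75 with an estimated correlation), and 5 rose, 13 fell and 9 were not called (5 and 13 adjusted over the list alone).

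**Figure D3:**
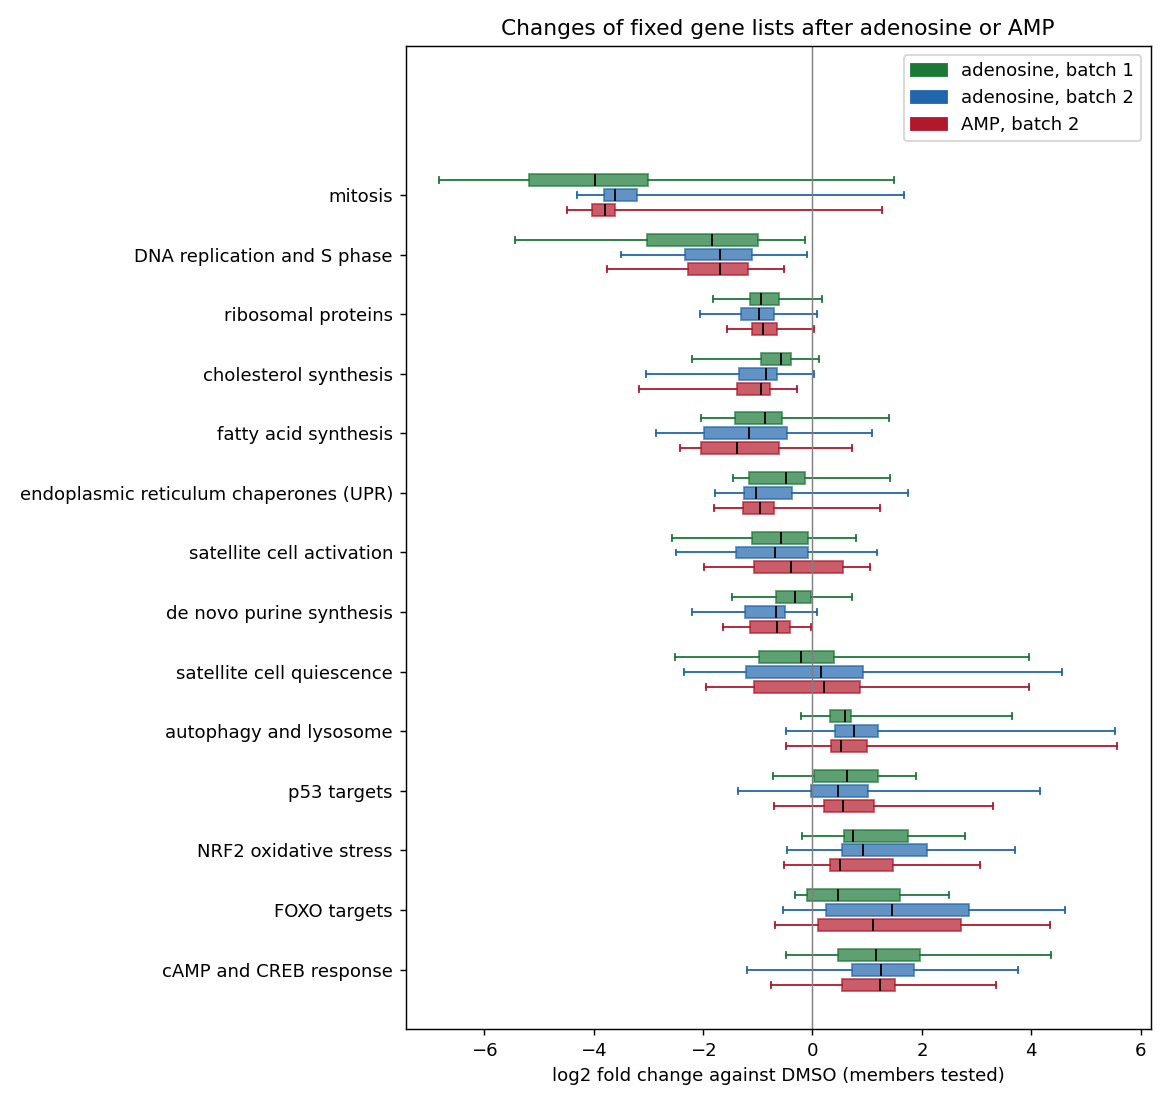
Log2 fold change over DMSO of the tested genes of 14 lists, for adenosine in batch 1, adenosine in batch 2 and AMP in batch 2. Boxes span the quartiles, lines mark medians and whiskers the full range, and mitosis has medians of -3.97, -3.61 and -3.79.

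Fold changes of AMP and of adenosine in batch 2 were correlated across 13063 genes (Pearson r = 0.965, Spearman rho = 0.954), with a slope of 0.891 and a covariance of 1.58. Both use the same 3 DMSO libraries, and simulated groups without any change gave r = 0.481 on average (0.514 at most over 20 simulations) and a covariance of 0.0426. Shared controls add the same covariance with or without real effects, so the difference of 1.54 estimates the shared effect. The same sign was found for 91.7% of genes, against 66.6% in these simulations. Against batch 1, whose controls are separate, AMP had r = 0.81. Genes rising with both compounds numbered 3999 (1537 if independent), those falling with both 3811 (1435), and 8 of 7818 went in opposite directions. The independent numbers leave out the shared controls, so part of the excess over them may come from these. Gpnmb had log2 fold changes of 5.52 with adenosine and 5.56 with AMP, and Ccnb1 of -4.31 and -4.48.

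AMP and adenosine differed directly in the levels of Acta2 and Cyp1a1. Acta2 (chromosome 19, 34241090 to 34255336) had 104 ± 59.9 CPM with AMP and 29.9 ± 14.8 CPM with adenosine (SD, n = 3 per group), a log2 difference of 1.84 (SE 0.35, adjusted p = 0.00442). Ablim1 was 3.31-fold higher, Bmper 3.28-fold higher, Cavin2 2.97-fold higher and Lpp 2.94-fold higher with AMP. Cyp1a1 had 2.98 ± 0.654 CPM with AMP and 25.8 ± 4.33 CPM with adenosine, a log2 difference of -3.07 (SE 0.23, adjusted p = 5.85e-06). The doses were 0.25 and 0.1 mM, so compound and dose changed together. A difference was called for 851 of 13063 genes, 590 higher and 261 lower with AMP, and 98 and 22 of these exceeded 2-fold. The count was 555 without AMP replicate 1, 519 without AMP replicate 2, 408 without adenosine replicate 3 and 1159 with a replicate block. With library totals 414 were higher and 257 lower. The groups did not overlap for 21.8% of tested genes, against 10% by chance. Kctd12, Tent5c, Rgcc and Hspa2 were 2.32-fold lower, 2.28-fold lower, 2.22-fold lower and 2.12-fold lower with AMP.

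Ccnd1 (chromosome 7, 144929931 to 144939869) was higher with AMP than with adenosine, at 415 ± 44.4 against 218 ± 45.9 CPM, a log2 difference of 0.98 (SE 0.11, adjusted p = 1.12e-04). Myf5 was 1.65-fold higher, Ncam1 1.86-fold higher and Hmga1 1.54-fold higher. Of 32 lists, 16 passed, 7 upward and 9 downward with AMP, and 0 in camera with an estimated correlation (17 lists had an unadjusted p under 0.05 with the preset correlation). Among the 16 genes of satellite cell activation, 6 were higher, 0 lower and 10 not called (8 and 0 adjusted over the list alone), with a median log2 difference of 0.27 (adjusted p = 5.37e-08, or adjusted p = 0.15 with an estimated correlation). The 16 genes of the TGF-beta and YAP response had a median of 0.46 (adjusted p = 4.24e-09, or adjusted p = 0.15 with an estimated correlation), and 7 were higher, 0 lower and 9 not called (10 and 0 adjusted over the list alone). Ankrd1 was 1.82-fold higher and Cyr61 1.66-fold higher. For extracellular matrix the median was 0.37 over 27 genes (adjusted p = 8.01e-09, or adjusted p = 0.28 with an estimated correlation), where 7 were higher, 0 lower and 20 not called (14 and 0 adjusted over the list alone). Tnc was 2.56-fold higher and Lama2 2.52-fold higher. Among the 17 genes of NF-kB and inflammation, 8 were higher, 0 lower and 9 not called (13 and 1 adjusted over the list alone), with a median log2 difference of 0.44 (adjusted p = 2.28e-09, or adjusted p = 0.15 with an estimated correlation). Tnfaip3 and Ccl2 were 1.83-fold higher and 2.04-fold higher. The 40 genes of ribosome biogenesis had a median of 0.22 (adjusted p = 4.01e-11, or adjusted p = 0.203 with an estimated correlation), and 13 were higher, 0 lower and 27 not called (24 and 0 adjusted over the list alone).

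Nqo1 was lower with AMP than with adenosine, at 151 ± 3.79 against 310 ± 20.1 CPM, a log2 difference of -0.99 (SE 0.09, adjusted p = 1.89e-05). Of the 16 genes of NRF2 oxidative stress, 0 were higher, 9 lower and 7 not called (0 and 11 adjusted over the list alone), with a median log2 difference of -0.33 (adjusted p = 8.35e-13, or adjusted p = 0.15 with an estimated correlation). The 17 genes of endoplasmic reticulum chaperones had a median of -0.19 (adjusted p = 2.16e-06, or adjusted p = 0.15 with an estimated correlation), and 0 were higher, 4 lower and 13 not called (1 and 9 adjusted over the list alone). Calr and Hspa5 were 1.52-fold lower and 1.42-fold lower. For heat shock the median was -0.19 over 13 genes (adjusted p = 2.26e-04, or adjusted p = 0.203 with an estimated correlation), where 0 were higher, 3 lower and 10 not called (0 and 5 adjusted over the list alone). Hspa1a, which can share reads with Hspa1b, was 1.97-fold lower. Of the 21 genes of autophagy and lysosome, 1 was higher, 4 lower and 16 not called (1 and 6 adjusted over the list alone), with a median log2 difference of -0.17 (adjusted p = 1.56e-04, or adjusted p = 0.15 with an estimated correlation). Ctsl was 1.46-fold lower. The 14 genes of hypoxia had a median of -0.21 (adjusted p = 0.0017, or adjusted p = 0.213 with an estimated correlation), and 0 were higher, 2 lower and 12 not called (1 and 4 adjusted over the list alone). Out of 47 genes of nuclear-coded oxidative phosphorylation, 0 were higher, 0 lower and 47 not called (0 and 0 adjusted over the list alone), with a median log2 difference of -0.11 (adjusted p = 3.77e-05, or adjusted p = 0.383 with an estimated correlation).

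The calls of 4 further lists for AMP against adenosine depended on single libraries or settings. Of the 74 genes of ribosomal proteins, 3 were higher, 0 lower and 71 not called (3 and 0 adjusted over the list alone), with a median log2 difference of 0.12 (adjusted p = 6.28e-04, or adjusted p = 0.682 with an estimated correlation). Its adjusted p was 0.546 without AMP replicate 1 and 0.23 without adenosine replicate 1, with medians of 0.0346 and 0.0581, and the median was 0.19 without AMP replicate 3 and 0.0661 with library totals. The 35 genes of the integrated stress response had a median of 0.11 (adjusted p = 0.0236, or adjusted p = 0.512 with an estimated correlation), and 7 were higher, 1 lower and 27 not called (9 and 4 adjusted over the list alone). Without AMP replicate 1 or adenosine replicate 2 it had an adjusted p of 0.285 or 0.239, and of 0.0633 among genes with a mean of at least 10 CPM. Its median was 0.0498 without AMP replicate 1, 0.169 without adenosine replicate 1 and 0.0679 with library totals. For the cAMP and CREB response the median was -0.32 over 15 genes (adjusted p = 0.0236, or adjusted p = 0.256 with an estimated correlation), where 0 were higher, 3 lower and 12 not called (2 and 5 adjusted over the list alone). This became 0.0725 without AMP replicate 2 and 0.188 without adenosine replicate 1, with medians of -0.188 and -0.198, and the median was -0.215 among genes with a mean of at least 10 CPM. Of the 25 genes of cholesterol synthesis, 1 was higher, 1 lower and 23 not called (1 and 2 adjusted over the list alone), with a median log2 difference of -0.10 (adjusted p = 0.0397, or adjusted p = 0.56 with an estimated correlation). The adjusted p was 0.508 without AMP replicate 3, 0.0892 without adenosine replicate 2 and 0.0585 among genes with a mean of at least 10 CPM. Its median was -0.0552 without AMP replicate 3 and -0.168 without AMP replicate 2. P2ry2 was 2.71-fold higher and Cd34 1.56-fold higher with AMP (adjusted p = 0.00103 and 8.30e-04). Adk and Myod1 were not called as differing between the compounds. Adk had a log2 difference of 0.06 (95% interval -0.16 to 0.28), and Myod1 of 0.34 (95% interval 0.12 to 0.57, adjusted p = 0.0687), the latter called with DESeq2 (adjusted p = 0.0331), with a replicate block (0.0411) and without AMP replicate 3 (0.00673). The 40 genes of mitosis had a median of -0.19 (adjusted p = 0.0614, or adjusted p = 0.794 with an estimated correlation), and 0 were higher, 1 lower and 39 not called (0 and 0 adjusted over the list alone).

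**Figure D4:**
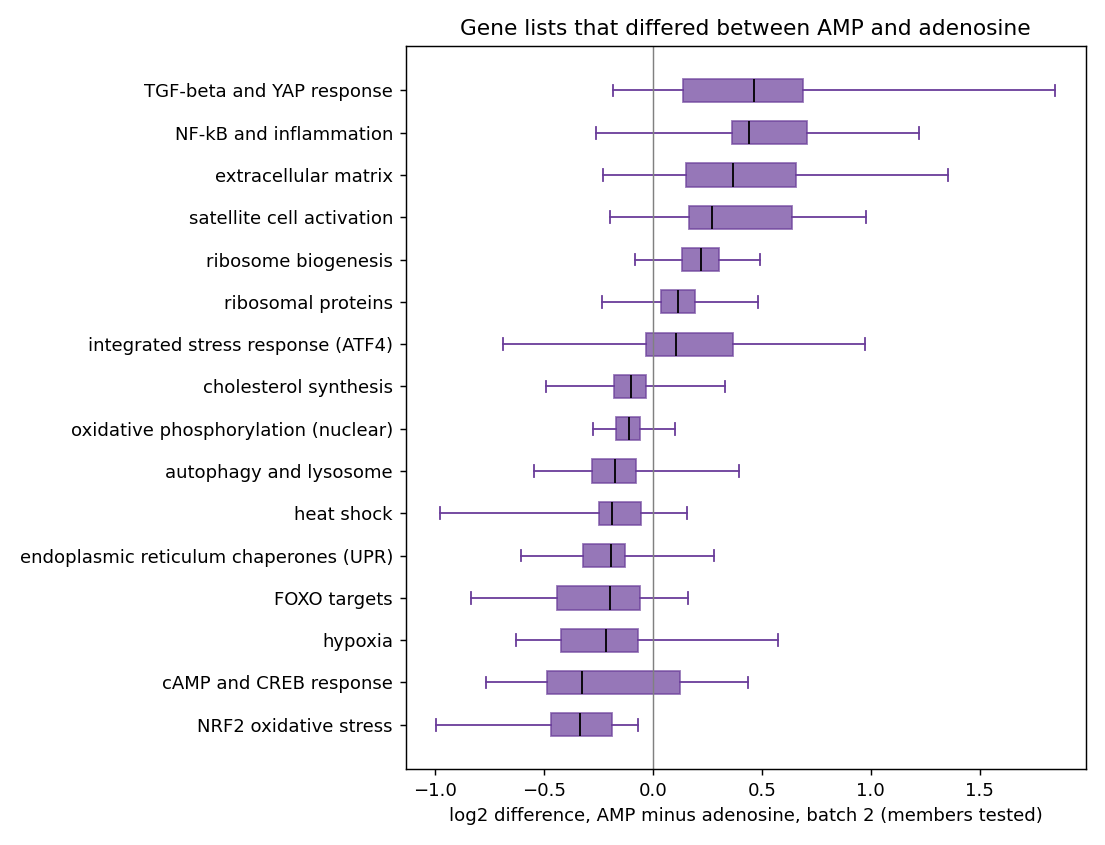
Log2 difference of AMP minus adenosine in batch 2 for the tested genes of the 16 lists past the threshold. Boxes span the quartiles, lines mark medians and whiskers the full range, and the NRF2 list has a median of -0.33.

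The adenosine effect itself differed between batches for Xdh, Txnip and Gal. Xdh had 7.43 ± 0.401 CPM with DMSO and 16.4 ± 3.34 CPM with adenosine in batch 1, against 1.29 ± 0.0806 and 20.4 ± 2.15 CPM in batch 2, a log2 difference of effects of 2.73 (SE 0.31, adjusted p = 9.50e-05). Txnip had a difference of 1.45 (SE 0.17, adjusted p = 1.12e-04). Dose and batch changed together, so they cannot be told apart here. Gal (chromosome 19, 3409919 to 3414472), which codes for the neuropeptide galanin, had 35.8 ± 18.9 CPM with DMSO and 225 ± 103 CPM with adenosine in batch 1, against 83.3 ± 8.96 and 120 ± 20.2 CPM in batch 2, a log2 difference of -2.24 (SE 0.42, adjusted p = 0.00331). The effect differed for 1560 of 13049 genes, with a higher log2 fold change in batch 2 for 821 and a lower one for 739. The count was 896 without DMSO replicate 2 of batch 2 and 1038 without DMSO replicate 3 of batch 2. With library totals the split was 1052 and 335. Dpep1, Dyrk1b and Rnf39 had differences of 3.01, 2.35 and 2.34, and Prkd1, Ptprg, P3h2 and Slc29a2 of -1.79, -1.60, -1.60 and -1.57. Myod1 did not differ detectably, at 0.02 (SE 0.19, adjusted p = 0.948).

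Between batches 13 of 32 lists differed in their adenosine effect, 5 upward and 8 downward in batch 2, and 0 in camera with an estimated correlation (14 lists had an unadjusted p under 0.05 with the preset correlation). Out of 17 genes of de novo purine synthesis, 0 were higher, 10 lower and 7 not called (0 and 14 adjusted over the list alone), with a median log2 difference of -0.55 (adjusted p = 3.64e-10, or adjusted p = 0.0613 with an estimated correlation). The 40 genes of ribosome biogenesis had a median of -0.37 (adjusted p = 1.00e-10, or adjusted p = 0.199 with an estimated correlation), and 0 were higher, 15 lower and 25 not called (0 and 23 adjusted over the list alone). For glycolysis the median was -0.40 over 17 genes (adjusted p = 1.17e-05, or adjusted p = 0.185 with an estimated correlation), where 0 were higher, 6 lower and 11 not called (0 and 11 adjusted over the list alone). Out of 12 genes of FOXO targets, 5 were higher, 0 lower and 7 not called (6 and 0 adjusted over the list alone), with a median log2 difference of 0.83 (adjusted p = 4.42e-05, or adjusted p = 0.162 with an estimated correlation). Among genes with a mean of at least 10 CPM this median was 0.373. Irs2 had a difference of 1.31. The 13 genes of pyrimidine synthesis and salvage had a median of -0.29 (adjusted p = 0.00517, or adjusted p = 0.199 with an estimated correlation), and 0 were higher, 3 lower and 10 not called (0 and 4 adjusted over the list alone). With library totals this median was -0.188. For autophagy and lysosome the median was 0.24 over 21 genes (adjusted p = 0.006, or adjusted p = 0.346 with an estimated correlation), where 4 were higher, 0 lower and 17 not called (7 and 0 adjusted over the list alone). Gpnmb and Ulk1 had differences of 1.88 and 1.14. Out of 21 genes of the interferon response, 5 were higher, 0 lower and 16 not called (5 and 0 adjusted over the list alone), with a median log2 difference of 0.86 (adjusted p = 0.00342, or adjusted p = 0.326 with an estimated correlation). Ddx58 had a difference of 1.93. The 16 genes of the TGF-beta and YAP response had a median of 0.39 (adjusted p = 0.00342, or adjusted p = 0.346 with an estimated correlation), and 5 were higher, 0 lower and 11 not called (6 and 0 adjusted over the list alone). Smad7 and Ctgf had differences of 1.75 and 1.35.

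The authors' deposited comparison of batch 1 listed 5699 genes with adjusted p under 0.05, 2869 higher and 2830 lower with adenosine. Of these, 5288 were also called here, all in the same direction.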

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

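The test of genes outside the ribosomal protein list, and scaling by library totals, were chosen only after the result was seen. Intervals here are over genes, which are not independent.

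The effect of adenosine differed between batches for 1560 genes by a direct test. Dose (0.05 and 0.1 mM) and batch changed together. Log2 differences are batch 2 minus batch 1. They were 3.012 for Dpep1, 2.729 for Xdh, 2.352 for Dyrk1b, 2.341 for Rnf39, 2.004 for Ddit4, 1.93 for Ddx58, 1.875 for Gpnmb, 1.753 for Smad7, 1.446 for Txnip, 1.353 for Ctgf, 1.312 for Irs2, 1.135 for Ulk1, 1.084 for Btg2 and 0.9549 for Foxo3. Negative differences were -2.238 for Gal, -1.792 for Prkd1, -1.605 for Ptprg, -1.6 for P3h2, -1.575 for Slc29a2, -0.8875 for Slc29a1, -0.8297 for Adk, -0.7819 for Mrto4, -0.7557 for Mthfd1l, -0.7516 for Impdh1, -0.7483 for Pfas, -0.7365 for Npm1, -0.6909 for Tpi1 and -0.5446 for Ldha. Ticrr had a difference of 2.49, which was not called without adenosine replicate 2 of batch 2 (adjusted p = 0.0532). Gbp2 had 1.323, with adjusted p = 0.0663 without DMSO replicate 2 of batch 1, 0.0629 or 0.0678 without DMSO replicate 2 or 3 of batch 2, and 0.053 in limma-voom. Pax7 had 0.5143, with adjusted p = 0.0514 or 0.0637 without adenosine replicate 2 or 3 of batch 2, 0.0616 or 0.0699 without DMSO replicate 2 or 3 of batch 2, 0.0527 without adenosine replicate 3 of batch 1 and 0.0661 without DMSO replicate 2 of batch 1.

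With the preset correlation 13 lists differed between batches. Median log2 differences were -0.548 for de novo purine synthesis, -0.294 for pyrimidine synthesis and salvage (-0.188 with library totals), -0.4 for glycolysis, -0.369 for ribosome biogenesis, 0.834 for FOXO targets, 0.236 for autophagy and lysosome, 0.859 for the interferon response and 0.388 for the TGF-beta and YAP response. With an estimated correlation none of these passed in camera, with adjusted p = 0.0613, 0.199, 0.185, 0.199, 0.162, 0.346, 0.326 and 0.346 in that order. For 5 lists the call depended on single libraries or settings. Nucleoside transport and purine turnover (-0.303) had adjusted p = 0.0652 without adenosine replicate 2 of batch 1 and 0.0649 among genes with a mean of at least 10 CPM, and its median was -0.123 without adenosine replicate 1 of batch 1 and -0.19 with library totals. Ribosomal proteins (-0.117) had 0.671 and 0.225 without DMSO or adenosine replicate 1 of batch 1, and 0.0632 and 0.146 without DMSO replicate 3 or adenosine replicate 1 of batch 2, and 0.0877 among genes with a mean of at least 10 CPM. Their median was -0.0298 without DMSO replicate 1, -0.246 without DMSO replicate 3 and -0.0217 without adenosine replicate 1 of batch 1, -0.0759 and -0.183 without adenosine replicate 1 or 3 of batch 2, -0.0603 among genes with a mean of at least 10 CPM and -0.00861 with library totals. NF-kB and inflammation (0.386) had 0.255 and 0.0652 without DMSO replicate 3 or adenosine replicate 2 of batch 1, and 0.111 without DMSO replicate 2 of batch 2, and its median was 0.214 and 0.599 without DMSO replicate 3 or 1 of batch 1. Cholesterol synthesis (-0.261) had 0.073 and 0.0652 without DMSO replicate 3 or adenosine replicate 2 of batch 1, and its median was -0.164 without the latter and -0.15 with library totals. Fatty acid synthesis (-0.347) had 0.061, 0.0536 and 0.0539 without DMSO replicate 3, adenosine replicate 1 or adenosine replicate 2 of batch 1. With all libraries, the adjusted p of these 5 lists in that order was 0.0305, 0.0149, 0.0336, 0.00365 and 0.0149, and with an estimated correlation 0.185, 0.789, 0.679, 0.679 and 0.507.

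Depth did not account for the difference between batches, since 1465 genes were called with all libraries thinned to the smallest total. A larger response of the same direction in batch 2 held for 921 called genes, or 59.7% (95% interval 57.2 to 62.2, n = 1542). Another 103 changed less in the same direction and 518 had opposite signs. Over all genes, 35 were called in opposite directions in both batches, so few of the 518 are called reversals. Bounds set beforehand were 75% and 60%. By value alone, the 59.7% counts against a larger response as the whole cause. Its interval, brought in after the value was known, leaves that open. Of 100 drawn splits of the libraries, 5 gave at least 1560 genes, the real one included, and the highest other gave 5955. The other 4 kept the groups of batch 2 and mixed those of batch 1, so they show the treatment itself. The splits therefore do not decide about chance, a reading adopted after the counts were known. Dose and batch may each contribute and cannot be told apart.

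Ribosomal protein genes were lower with adenosine in batch 1. Their median log2 fold change was -0.949 over 74 genes (adjusted p = 9.84e-26, or 0.316 with an estimated correlation). A set of genes outside the list had a median of -0.114 (95% interval -0.16 to -0.0464, n = 374). They were no longer than its longest member and above its least abundant ones in level. They were not matched in length or level, so this cannot decide about either as a cause. Members with at most 1 annotated pseudogene of their name had -0.991 (95% interval -1.09 to -0.717, n = 32). This leaves open reads shared with pseudogenes of other names. Without the 6 genes like ribosomal RNA the median was -0.948 (95% interval -1.04 to -0.736). A lower relative level of these transcripts may be biological, a hypothesis found and tested on the same data.

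AMP and adenosine differed in batch 2 at 851 genes. Of 846 of these with a value in batch 1, 86.5% (95% interval 84 to 88.8) differed in the direction opposite to the adenosine change of batch 1, against 63.9% of all genes, as a weaker response to AMP would give. With libraries thinned to the smallest total 848 genes were called, which argues against depth. Of the 851 genes, 631 changed less in the same direction with AMP, 87 changed more and 133 had opposite signs (8 called with both compounds). A weaker response to AMP may cover most, but not NF-kB and inflammation (median 1.52 with AMP, 1.19 with adenosine). Compound and dose cannot be told apart.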

How the results depend on the processing

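Scaling by library totals and leaving out the 6 genes like ribosomal RNA were chosen only after the data were seen.

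Over 200 settings of 12 counts and correlations, 189 stayed within their tolerance and 11 moved. For a count the tolerance was a factor of 1.5 either way, and for a correlation 1 jackknife SE from fits that each left out 1 library, 0.0318 between batches and 0.0108 between compounds. Of 1248 settings of 90 list results, 1112 kept their call and 136 lost it, 90 of them with a correlation estimated from the data. Of 5404 settings of 286 gene results, 5365 kept their call, 30 lost it and 9 gained it. No called result turned direction in its test, but the median of pyrimidine synthesis and salvage for adenosine in batch 1, called at -0.157, was 0.0423 with library totals, where the list was not called.

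With a correlation estimated from the data, camera called 0 lists for adenosine in batch 1 or batch 2, AMP, AMP against adenosine or the difference between batches. With the preset correlation 23, 21, 20, 17 and 14 lists had an unadjusted p under 0.05. Estimated correlations within lists rest on few libraries. The correlation of adenosine fold changes between batches was 0.884 among genes with a mean of at least 10 CPM, a filter that leaves fewer, more abundant genes.

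Leaving out 1 library at a time gave 4326 to 4912 genes for adenosine in batch 1, 8411 to 8633 in batch 2, 7786 to 8310 for AMP, 408 to 991 for AMP against adenosine and 896 to 2064 for the difference between batches. For AMP against adenosine 851 became 555 and 519 without AMP replicate 1 or 2, and 408 without adenosine replicate 3. For the difference between batches 1560 became 896 and 1038 without DMSO replicate 2 or 3 of batch 2. The cause was not tested beyond the smaller number of libraries. The correlations ranged from 0.8074 to 0.8439 between batches and from 0.9569 to 0.9684 between compounds. List counts ranged over 19 to 22, 21 to 21, 19 to 21, 14 to 18 and 10 to 16 in the same order.

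With the replicate number as a block, 5004, 9239, 8742, 1159 and 1725 genes were called in the order above. DESeq2 called 5672, 8939, 8417, 1058 and 1889. Thinned counts gave 5361, 9021, 8519, 848 and 1465, so depth within the range of these libraries changed little.

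Without TMM factors 67.4%, 68.7% and 69.9% of called genes were higher with adenosine in batch 1, adenosine in batch 2 and AMP, against 50.1%, 50.3% and 51.4% with them. No spike-in is mentioned, so the balance of rises and falls is not fixed by these data.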

Other observations

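The tests of imprinted genes and of receptor targets were run on gene sets picked after values had been seen, and both are hypotheses found in the same data.

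In each comparison with 3 libraries per group, 1 of 10 splits gave as many genes as the real grouping, and the highest other gave 0. The real counts were 5420 and 9067 for adenosine in batches 1 and 2, 8564 for AMP and 851 for AMP against adenosine. With 10 splits the share cannot fall under 0.05.

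The imprinted genes H19, Meg3, Rian and Cdkn1c stood out among large changes, so 28 other imprinted genes were tested. Their median absolute log2 fold change was 0.718 in batch 1, against 0.483 for random lists of like expression (percentile 96.3), and 0.944 against 0.62 with adenosine in batch 2 (percentile 96.5). They went both ways, with 8 rises and 7 falls in batch 1. Mest rose by log2 fold changes of 2.29 and 2.39 and Slc38a4 fell by 2.03 and 3.27 in the 2 batches, both chosen after their values were seen. In size of change, imprinted genes may respond more strongly than others of like expression. The share called in batch 2 does not point that way.

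Cyp1a1, a target of the aryl hydrocarbon receptor, was lower with AMP than with adenosine. The median log2 difference of 7 other targets was -0.528, against 0.0017 for random lists of like expression (percentile 0.02 of 10000 lists). Cyp1b1 (mean of 1.96 CPM) had -2.31 (adjusted p = 0.00821) and Tiparp -0.81 (adjusted p = 2.39e-04). Ahrr, Aldh3a1, Nfe2l2, Cyp2s1 and Scin did not pass (adjusted p = 0.113, 0.102, 0.131, 0.912 and 0.876). Cyp2s1 rose by log2 fold changes of 3.26 with adenosine and 3.14 with AMP in batch 2, and Scin by 2.78 and 2.58. With adenosine Cyp1a1 had log2 fold changes of -1.02 in batch 1 (adjusted p = 0.2) and 4.97 in batch 2, and Cyp1b1 of -5.50 and 2.71. In batch 1 Ahrr (-0.59), Aldh3a1 (-0.60), Tiparp (-0.27) and Cyp2s1 (1.43) were not called (adjusted p = 0.535, 0.0711, 0.191 and 0.214), while Nfe2l2 (0.63) and Scin (1.53) rose. Drive on this receptor was not measured.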
